A study of Mus musculus with 4 samples.

How the data were processed

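Total RNA of 4T1 mouse mammary carcinoma cells was measured on one-colour Affymetrix arrays, with 2 CD44v8-10-positive and 2 CD44v8-10-negative samples, assigned to groups from the sample labels. The submitters' processing notes name GCOS, the Affymetrix operating software, without a role. The deposited values, 1 per probe set and array, were linear intensities: they ran from 0.1 to 22695.6 over 45101 probe sets and were never negative. The summary method, background correction and any scaling behind them are not given in the sources used here. The 2% trimmed means of the arrays were 237, 220, 196 and 345, which differ by more than 5%, so the values were treated as not scaled to each other. Array control probe sets gave 3' to 5' ratios of 1.17 to 1.35 for actin and 0.778 to 0.839 for Gapdh.

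Probe sets were named from the platform annotation of 2016. Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 several and 9160 none; probe sets with several or no symbols were not named. By gene number 34741 of those with 1 symbol were matched to the reference gene table, which changed 0 symbols. No genome sequence was used, so probe set positions within genes, including the Cd44 variant exons, were not analysed.

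The tests, gene lists, named-gene rule and most alternatives were chosen before the data were examined. The design allowed for intensities that were already scaled or not, and its rule for values not scaled made quantile normalization between arrays the main setting. Normalized values were transformed as log2(value + 16). Control probe sets were then removed, and probe sets whose mean over the 4 arrays was below the 40th percentile were left out, which left 27022. The filter level was a log2 value of 5.15, or a normalized signal of 19.4. For each gene the probe set with the highest mean was used, giving 11956 genes, of which 5833 had more than 1 probe set above the filter. Fold changes are on the log2(value + 16) scale, which understates differences of dim genes.

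Groups were compared in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg over all genes, threshold 0.05). The fit had 12.2 degrees of freedom, prior included, and the median standard error of a log2 fold change was 0.24. Of 28 gene lists, the 25 with at least 5 tested members were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. Each list was also adjusted over the list alone. The procedure was tested on simulated data: 20 simulations of the comparison of positive with negative cells, over 11956 genes with 200 changed. It recovered 40.7% of genes changed by a log2 value of 1, 94.1% at 2, 99.5% at 3 and 100% at 4, with 5.88% false among the called genes. With 200 genes changed, the adjusted threshold was easier to pass than in these data, where 9 genes passed. The simulated spreads were also drawn from the fitted model, so these shares may overstate recovery in this comparison. In the same simulations a list shifted by 0.5 was found in 20 of 20 by camera with its preset correlation and in 0 of 20 with an estimated correlation, and no unshifted list was called by either. The simulated genes varied independently of each other. These runs therefore do not show how often either setting calls unshifted lists whose members vary together.

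The named genes were Cd44, Esrp1, Esrp2, Slc7a11 and Slc3a2 whatever their values; the 12 highest and 12 lowest by log2 fold change among genes past the threshold with separated groups, filled where fewer passed by the largest fold changes among separated genes with an unadjusted p under 0.05; and, from each list that passed camera or had at least 2 members past the threshold, up to 4 passing members, or the 2 brightest members where none passed. As run, lists with only 1 member past the threshold were taken as well, which added no further named gene. Clone and predicted gene names were counted but not named. Cdh1, Krt8, Krt18, Vim, Zeb2, Cldn4, Fn1, S100a4, Pkp1 and Sfn, and the remaining named members of lists and markers, were chosen after their values were seen.

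Alternatives were median centring, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, a filter on the higher group mean, the mean of a gene's probe sets, less specific probe sets (identifiers ending in _x_at or _s_at) left out, every probe set on its own, eBayes without the trend or with a robust prior, the replicate number as a block, and leaving out each array in turn. Values with no scaling and arrays scaled to one 2% trimmed mean were added after seeing the data. Lists were not tested with every probe set on its own.

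All tests of explanations were chosen after the results were seen, and the rules of 3 were revised later. For fibroblasts behind Postn the rule was set 3 times. The first, collagen signals against the signal of Postn, argued against them but compared different probe sets. The second, the bounds of the 5 tested markers with at least 3 required to be brighter than the median tested gene, left the question open because 0 were. The third, used here, sets the bounds of the tested markers and the differences of all 13 markers against the lower bound of Postn and argues against them. For array brightness behind the interferon genes, the first rule, on trimmed means, argued against it, and the rule used here also needs the medians to agree, which left it open. For dilution, the median of the epithelial genes was replaced by their standard deviation, and both rules argued against it. Much of that standard deviation came from genes already called, so it does not decide.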

Results

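Gene expression was measured in 4T1 cells, a mouse mammary carcinoma line, divided by whether they carried CD44v8-10, a splice form of the cell-surface receptor CD44 that contains variant exons. Total RNA from 2 CD44v8-10-positive and 2 CD44v8-10-negative samples was hybridised to 4 one-colour Affymetrix arrays of 45101 probe sets. The comparison asked how far the expression profiles of the positive and negative cells differed. The deposited arrays were not equally bright: their trimmed mean intensities were 237 and 220 in the positive samples and 196 and 345 in the negative samples, so they were quantile normalized. After the filter on dim probe sets, 11956 genes were tested. Across these genes the Pearson correlation was 0.972 between the positive arrays and 0.981 between the negative arrays, and the highest of any pair, 0.985, joined positive replicate 1 with negative replicate 1.

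CD44v8-10-positive cells had more mRNA of Esrp1, an RNA-binding protein that directs epithelial patterns of splicing, including the inclusion of Cd44 variant exons. Its normalized signal was 1357 ± 11.7 in CD44v8-10-positive cells and 47.5 ± 23.5 in negative cells (mean ± SD, n = 2 each). The fitted difference, on the log2(value + 16) scale, was 22.4-fold. On the same scale Rab25, a small GTPase of epithelial vesicle recycling, was 9.50-fold higher in the positive cells. Its negative arrays lay below the filter level of 19.4, so this fold is no exact size. Postn, the secreted matrix protein periostin, was 7.03-fold higher. The tight junction claudins Cldn7 and Cldn3, the basal keratin Krt14, the laminin chain Lama3, the serpin Serpinb5 and the epithelial adhesion molecule Epcam were also higher, by 4.96-fold for Cldn7 down to 2.53-fold for Epcam. The signals of the abundant simple-epithelial keratins Krt8 and Krt18 and of E-cadherin, Cdh1, overlapped between the groups.

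These were the 9 genes past an adjusted p of 0.05 (limma, two-sided, Benjamini-Hochberg over 11956 genes), and each differed by at least 2-fold. Esrp1 had a log2 fold change of 4.48 ± 0.27 (SE) with an adjusted p of 1.03e-05 by limma. Rab25 followed with 3.25 ± 0.31 and an adjusted p of 0.000639, and Postn with 2.81 ± 0.25 and 0.000582. The 2 claudins rose by 2.31 ± 0.22 (Cldn7, adjusted p 0.000639) and 1.96 ± 0.20 (Cldn3, adjusted p 0.000851), and the 4 probe sets of Cldn3 gave 1.86 to 2.02. Krt14 rose by 1.97 ± 0.24 (adjusted p 0.00547) and Epcam by 1.34 ± 0.18 (adjusted p 0.0118). Serpinb5 rose by 1.84 ± 0.26 (adjusted p 0.0194) and Lama3 by 1.66 ± 0.25 (adjusted p 0.0302). In all 9 genes both positive arrays lay above both negative arrays. The Rab25 signal in the negative arrays, 5.78 and 6.13, was below the filter level of 19.4, so its fitted fold is no exact size and depended on the pseudocount: the log2 fold change was 4.80 with a pseudocount of 1 and 1.87 with 64, where that of Esrp1 was 3.69. Epcam lost the call without either positive array (limma adjusted p up to 0.258), Krt14 without positive replicate 2 (0.0838), Serpinb5 without positive replicate 1 (0.141) or negative replicate 1 (0.120), and Lama3 whichever array was left out (0.0621 to 0.272). With arrays scaled to one trimmed mean Lama3 (0.0715) and Serpinb5 (0.0603) lost the call, with the mean of a gene's probe sets Epcam (0.189) and Serpinb5 (0.363), and with every probe set tested on its own Epcam (0.0554), Serpinb5 (0.0899) and Lama3 (0.143). With no scaling between arrays, and without the intensity trend, Esrp1 and Rab25 were those of the 9 that passed, and with no filter Esrp1, Cldn7 and Cldn3.

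**Figure D1:**
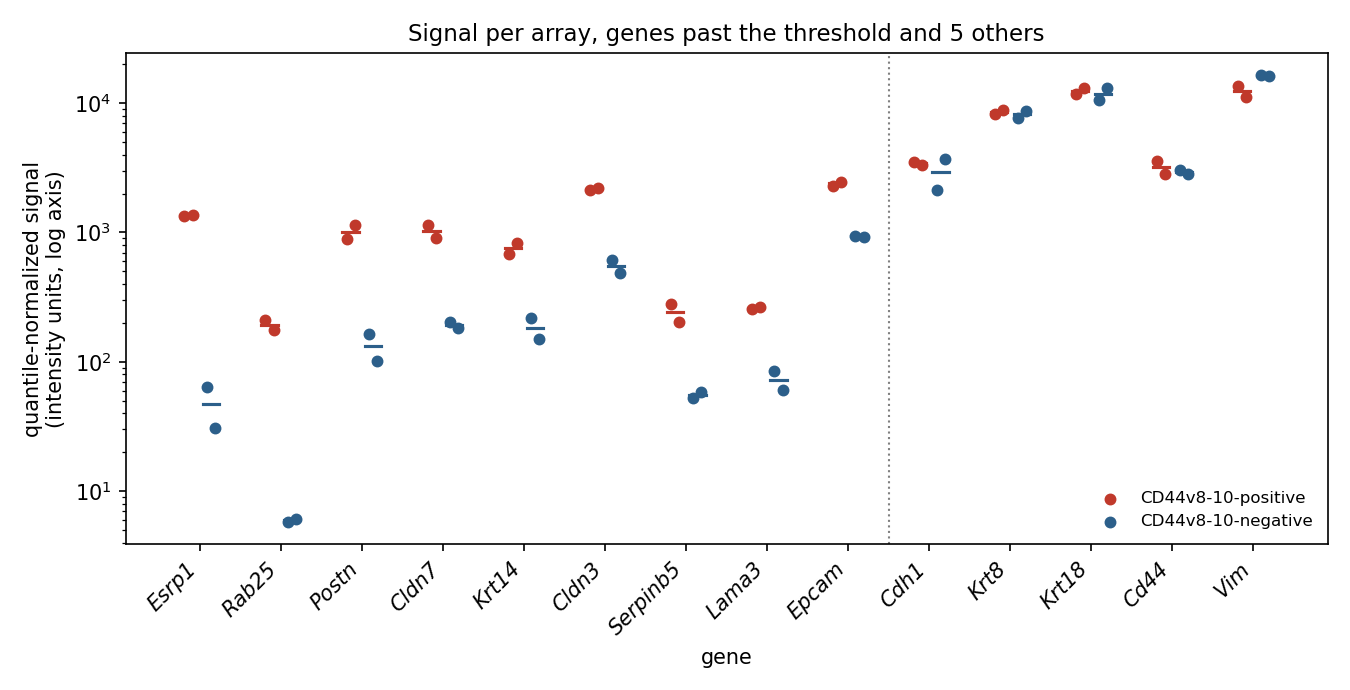
Quantile-normalized signal (intensity units, log axis) of the 9 genes past the threshold, left of the dotted line, and of 5 further genes in each of the 4 arrays. Points are single arrays and bars are group means; Esrp1 lay at 1348 and 1365 in the positive arrays and at 64.1 and 30.9 in the negative arrays.

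Under the main settings no gene was called lower in the positive cells (limma, 0 genes), and without negative replicate 2 S100a4 was (adjusted p 0.00418), while at an unadjusted p under 0.05 there were 321 genes higher and 211 lower. Together these were 532 of the 11956 genes tested, a smaller share than the 0.05 expected with no difference. Groups did not overlap in 3862 genes, or 32.3%, where chance gives 33.3% for 2 arrays against 2. The 12 genes with the lowest log2 fold changes among those with separated groups were Hoxa7, Trpc4, Psd, Zfp184, Srms, Nptx1, H1f6, Akr1c13, Spo11, Loxl3, Rbp2 and Olfml2b, and none of them passed under these settings. In 6 of them, Hoxa7, Trpc4, Psd, Srms, H1f6 and Spo11, both positive arrays were below the filter level of 19.4, so their fitted folds are no exact sizes. The homeobox gene Hoxa7 had a log2 fold change of -1.72 (limma adjusted p 0.292), with mean signals of 10.9 in positive and 71.1 in negative cells. The neuronal pentraxin Nptx1 had -1.29 (adjusted p 0.245) and the lysyl oxidase family member Loxl3 -1.21 (adjusted p 0.363). With the replicate number as a block, Nptx1 (limma adjusted p 0.0435), Pmp22 (0.0435) and S100a4 (0.0439) were called lower. The labels give no shared day for arrays of the same number. On the higher side Engase, at 1.76 (adjusted p 0.359), the epithelial clathrin adaptor subunit Ap1m2, at 1.70 (adjusted p 0.335), and the chemokine receptor Ccr2, at 1.64 (adjusted p 0.596), completed the 12 named genes without passing; their negative signals were all below the filter level, which leaves their folds inexact too.

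Cd44 itself differed little. The log2 fold change of its brightest probe set was 0.11 (95% interval -0.26 to 0.48, limma adjusted p 0.985), and it was -0.06 with no scaling between arrays and -0.05 without positive replicate 1. Its other 2 probe sets above the filter gave 0.14 and 0.40. Which exons these probe sets cover could not be checked here, so they do not test the division of the cells by CD44v8-10. Esrp2, the paralog of Esrp1, had a log2 fold change of 0.64 (unadjusted p 0.0160, adjusted p 0.985 by limma), and its second probe set gave 0.29. Among 36 splicing regulators tested, Esrp1 alone passed the threshold, over all genes and adjusted over the list alone. Of these genes 18 lay above 0 and 18 below, with a median of 0.0021 and a mean of 0.07, while camera gave the list a downward direction (adjusted p 0.674).

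Of 47 genes of epithelial junctions and differentiation tested, 40 lay above 0 and 42 did not pass over all genes, with a median log2 fold change of 0.44 and quartiles of 0.08 and 0.81. The 5 that passed over all genes were Esrp1, Rab25, Cldn7, Cldn3 and Epcam, and 16 passed adjusted over the list alone, all higher, among them Cldn4 (1.16, past the threshold over all genes with arrays centred on their median, limma adjusted p 0.0389) and the transcription factor Ovol1 (0.91). The list passed camera with its preset correlation (adjusted p 5.54e-19), but had an adjusted p = 0.557 with an estimated correlation and an adjusted p of 0.263 by fry. Desmosome and stratified keratin genes had 16 of 18 above 0 and a median of 0.74 (camera adjusted p 1.91e-11, and adjusted p = 0.557 with an estimated correlation). Krt14 passed over all genes, and 6 genes passed adjusted over the list alone, including the plakophilin Pkp1 (1.16) and stratifin, Sfn (1.11, past the threshold over all genes with arrays centred on their median, limma adjusted p 0.0391). Against these stood Cdh1, at 0.28 (95% interval -0.21 to 0.76; -0.12 without negative replicate 1), Krt8, at 0.06 (-0.23 to 0.34; -0.03 without negative replicate 1), and Krt18, at 0.08 (-0.20 to 0.37; -0.06 without negative replicate 1).

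**Figure D2:**
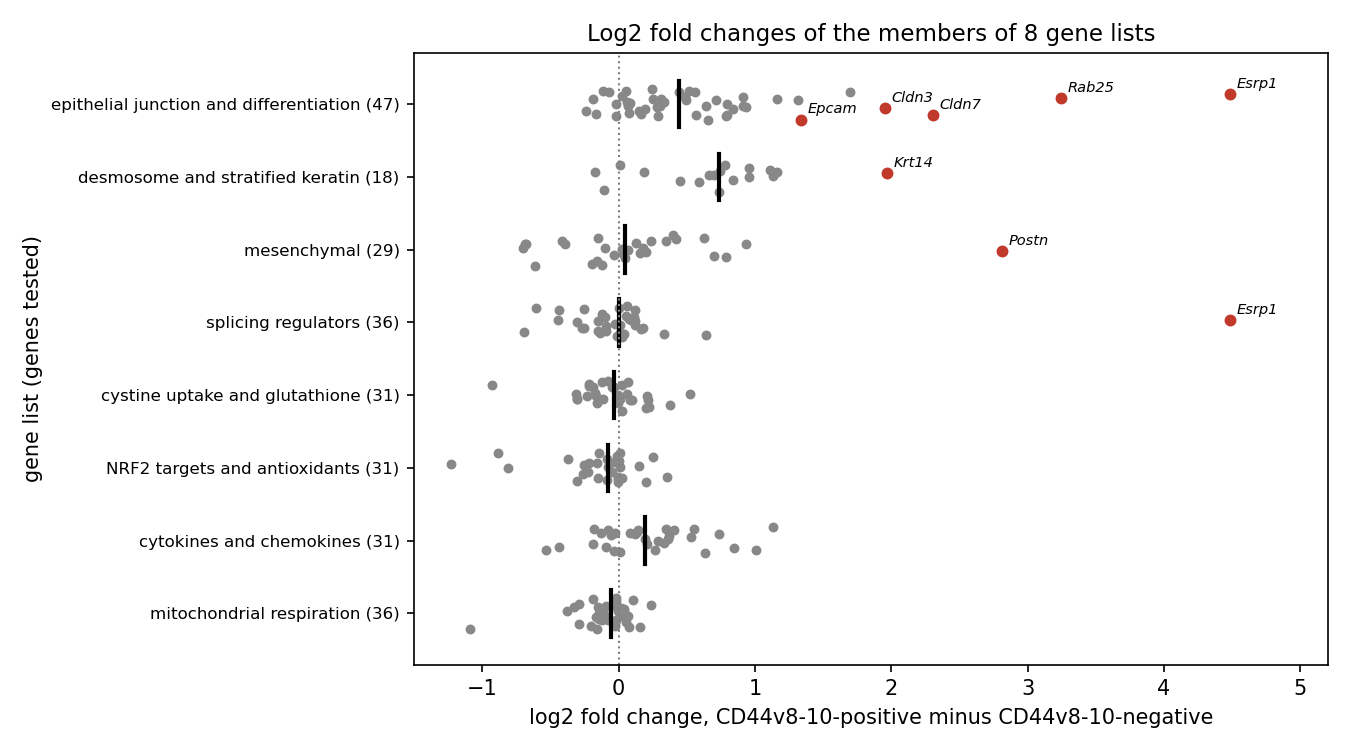
Log2 fold changes (CD44v8-10-positive minus CD44v8-10-negative) of every tested member of 8 gene lists; red points passed the threshold over all genes and black bars are list medians. The epithelial and desmosome lists have medians of 0.44 and 0.74, and the mesenchymal list has a median of 0.04.

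Mesenchymal genes did not move as a group. Of 29 tested, 17 lay above 0 and 12 below, with a median of 0.04 (camera adjusted p 0.819), and Postn was the one gene that passed over all genes. Beside it, the 5 fibroblast markers tested had log2 fold changes from -0.94 (Pdgfra) to 0.37 (Pdpn), with Col1a2 at 0.04. Adjusted over the list alone, 2 were higher, Postn and fibronectin, Fn1, and 3 lower: vimentin, Vim, Sparc and S100a4. Fn1 had a log2 fold change of 0.70 (limma adjusted p 0.420), although its other probe set gave 0.15. Vim had -0.39 (unadjusted p 0.00757, adjusted p 0.919), S100a4 -0.70 (adjusted p 0.278, and 0.00418 without negative replicate 2), and the repressor of epithelial genes Zeb2 -0.69 (adjusted p 0.982).

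The cystine transporter that CD44 variants have been linked to showed no detectable difference in mRNA. Its catalytic subunit Slc7a11 had a log2 fold change of -0.0023 (95% interval -0.55 to 0.54, limma adjusted p 1.00), which was 0.0088 with arrays centred on their medians and 0.20 with the mean of its probe sets. A second Slc7a11 probe set above the filter gave 0.40 ± 0.38 (SE), with overlapping signals of 90.6 and 124 in the positive and 44.9 and 124 in the negative arrays. The heavy chain Slc3a2 had 0.08 (95% interval -0.41 to 0.57, limma adjusted p 0.990), and -0.05 with no scaling between arrays. Of 31 genes of cystine uptake and glutathione metabolism, 13 lay above 0 and 18 below, none passed limma over all genes or adjusted over the list alone, 1 was lower at an unadjusted p under 0.05, and the median was -0.04 (camera adjusted p 0.365). NRF2 targets and antioxidant genes had 23 of 31 below 0 and a median of -0.08, with 0 genes called by limma and 2 lower at an unadjusted p under 0.05. This list passed camera as lower (adjusted p 0.0129, and adjusted p = 0.557 with an estimated correlation), but not without positive replicate 2 (0.0680) or without negative replicate 2 (0.0503), nor with the mean of a gene's probe sets (0.188), arrays centred on their medians (0.0566) or the less specific probe sets left out (0.0519). Its brightest members were ferritin, Fth1, at -0.23, and thioredoxin, Txn1, at -0.08; these were 0.03 and 0.18 with arrays centred on their medians, and Txn1 was 0.14 with arrays scaled to one trimmed mean.

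Cytokines and chemokines had 21 of 31 genes above 0 and a median of 0.20 (camera adjusted p 0.0129, and adjusted p = 0.557 with an estimated correlation). None passed over all genes by limma, 5 were higher at an unadjusted p under 0.05, and 1, the epithelial cytokine Tslp at 1.13, passed adjusted over the list alone. The brightest members were the chemokine Cxcl16, at 0.63, and the growth factor Hbegf, at 0.12, which was -0.08 with no scaling between arrays. The list did not pass without positive replicate 1 (adjusted p 0.891) or with no filter (0.0944). Beside it, 6 of 7 tested macrophage markers lay above 0 with a median of 0.34 (camera adjusted p 0.0666, and adjusted p = 0.568 with an estimated correlation). That list passed in 6 of 15 other settings, with its lowest adjusted p, 0.00198, without positive replicate 1; the brightest marker, Cd14, had mean signals of 242 in positive and 184 in negative cells. In that setting Laptm5 was called (log2 fold change 3.05, limma adjusted p 0.0328) by a probe set with signals of 14.6 and 264 in the positive and 8.68 and 30.9 in the negative arrays, so that 1 positive array carried the difference, while the probe set tested with all 4 arrays gave -0.01. Mitochondrial respiration genes had 25 of 36 below 0 and a median of -0.06, with 0 genes called by limma and 2 lower at an unadjusted p under 0.05. The list passed camera as lower (adjusted p 0.0129, and adjusted p = 0.731 with an estimated correlation). It did not pass without positive replicate 1 (0.0503), positive replicate 2 (0.0835) or negative replicate 1 (0.0677), nor with arrays scaled to one trimmed mean (0.416), centred on their medians (0.373) or without the intensity trend (0.0639). Its brightest members were Atp5b, at 0.05, which was -0.04 without positive replicate 2, and Cox7a2, at -0.17, which was 0.0015 with arrays scaled to one trimmed mean.

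The remaining lists did not pass camera under the main settings. Extracellular proteases and inhibitors had 20 of 30 genes above 0 and a median of 0.09 (adjusted p 0.0618); Serpinb5 passed over all genes, and Serpinb5, Mmp10 (0.97) and Adamts1 (0.78) passed adjusted over the list alone, and the list passed in 5 of 16 other settings: the filter at the 60th percentile (0.0134), the mean of a gene's probe sets (0.0436), one trimmed mean (0.0453), and without positive replicate 2 (0.0288) or negative replicate 1 (0.0387). ATF4 and unfolded protein response genes had a median of -0.09 over 35 genes (adjusted p 0.0719); the list passed as lower without positive replicate 2 (0.00106) or negative replicate 1 (6.39e-06), and its direction was upward without negative replicate 2 (0.364). Glycolysis and hypoxia genes had a median of 0.05 over 32 genes (adjusted p 0.721), with the oxygen sensor Egln3, at -1.09, lower adjusted over the list alone. In the lists that follow limma called no gene over all genes or adjusted over the list alone, with at most 4 higher and 1 lower per list at an unadjusted p under 0.05. Proliferation genes had a median of 0.07 over 44 genes (adjusted p 0.800), ribosomal proteins 0.02 over 26 (0.885; 0.0173 with no scaling and 0.0453 with one trimmed mean, both upward), reference genes 0.02 over 15 (0.721) and cholesterol synthesis 0.09 over 20 (0.218; 0.00358 without negative replicate 1). Interferon response genes had a median of 0.10 over 33 genes (camera adjusted p 0.390). That list passed as higher without positive replicate 2 or negative replicate 1. Its direction was downward without positive replicate 1 or negative replicate 2. Class I antigen presentation had a median of 0.07 over 17 genes (camera adjusted p 0.721), immediate early genes 0.08 over 27 (0.384) and p38 stress signalling 0.09 over 24 (0.218). Without negative replicate 2 the last 2 passed as higher. Integrins and adhesion genes had 0.10 over 30 (adjusted p 0.867). TGF-beta and Wnt response genes had -0.02 over 34 (adjusted p 0.800) with a mean of 0.0034, and stem and mammary progenitor genes 0.01 over 25 with a downward direction in camera (0.885). Fibroblast markers had a median of 0.04 and a mean of -0.18 over 5 genes, downward in camera (adjusted p 0.390), and endothelial markers -0.10 over 5 (0.721). Of the adipocyte, erythroid and lymphocyte markers, 0, 1 and 1 genes were above the filter, too few to test.

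Of the 25 lists tested, 5 passed camera with its preset correlation, 3 higher and 2 lower, and 0 passed camera with an estimated correlation or fry (lowest adjusted p 0.263). Fry's test for change in either direction called the epithelial list (adjusted p 0.00246). The 2 arrays per group limit the precision, and nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.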

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

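Values with no scaling between arrays and with one trimmed mean were chosen after seeing the data; the other alternatives were planned. The planned quantile normalization became the main setting, and a robust prior was not run for lists. The 9 called genes had separated groups, so most alternatives could not turn their direction. Over 18 alternatives all 9 called genes stayed higher in positive cells wherever tested, and Esrp1 passed in each (limma adjusted p up to 0.0242). Against 9 genes, 3 passed with no scaling (Esrp1, Rab25 and 1 other), 15 with median centring (all 9 kept), 7 with one trimmed mean (Lama3 and Serpinb5 lost), 8 with the mean of a gene's probe sets (Epcam and Serpinb5 lost, 1 other gained), 8 with the filter at the 60th percentile (Rab25 was filtered out), 3 with no filter (all among the 9) and 2 without the intensity trend (Esrp1 and Rab25); every one of these was higher, and the counts at 2-fold or more were the same. With every probe set tested, 9 passed, from 6 genes. With no filter 18193 genes were tested; for the other settings the cause was not tested. The replicate block gave 18 genes, 15 higher, Moxd1 and Cldn4 among them, and 3 lower (Nptx1 with an adjusted p of 0.0435, Pmp22 and S100a4), with 17 at 2-fold or more, and changed no list count; same-numbered arrays correlated by 0.116 in their deviations over only 2 pairs, and the labels give no shared day. Leaving out 1 array, with the lone array assumed to vary like the other group, gave 6 to 16 genes: 16 without positive replicate 1 (6 of the 9 kept), 6 without positive replicate 2, 9 without negative replicate 1 and 10 without negative replicate 2, of which 1 was lower (S100a4). At 2-fold or more the range was also 6 to 16, with 9 without negative replicate 2. Esrp1, Rab25, Postn, Cldn7 and Cldn3 passed each time. The median log2 fold change of all genes moved from 0.03 to -0.15 with no scaling.

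Against 5 lists, 3 passed with median centring, 0 with camera's estimated correlation, 0 with fry, and 4 to 8 with 1 array left out (8 without negative replicate 1). The epithelial and desmosome lists passed in 16 of 16 camera settings, cytokines in 14, NRF2 targets in 11 and mitochondrial respiration in 10.

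Signs of small, uncalled differences turned. With no scaling Cd44 was -0.057, Hbegf -0.084 and Slc3a2 -0.048. With one trimmed mean Cox7a2 was 0.0015 and Txn1 0.14, and with median centring Cox7a2 was 0.043, Fth1 0.031, Slc7a11 0.0088 and Txn1 0.18. With the mean of a gene's probe sets Slc7a11 was 0.20 and Txn1 0.33. With 1 array left out, values ran from -0.042 to 0.15 for Atp5b, -0.048 to 0.26 for Cd44, -0.12 to 0.70 for Cdh1, -0.046 to 0.29 for Hbegf, -0.065 to 0.25 for Krt18, -0.030 to 0.16 for Krt8, -0.24 to 0.40 for Slc3a2, -0.20 to 0.041 for Slc7a11 and -0.18 to 0.030 for Txn1. The cause was not tested. Of 767 alternatives over 44 named genes, 701 kept direction and side of the threshold, 36 lost and 6 gained the call, and 24 reversed. Only the 9 called genes could lose the call, so the 36 losses all fell on their alternatives. Lama3 lost it in 9 of 18, Serpinb5 in 8 of 18 and Epcam in 7 of 18, while Esrp1 lost it in 0. The 12 highest and 12 lowest of these named genes were chosen for separated groups, so most alternatives could not reverse them. Low signal over background limits the dimmest genes: the Rab25 probe set fell under the 60th percentile and was not tested there.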

Other observations

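All tests of explanations in this part were chosen after the results were seen. Lama3 encodes a chain of laminin-332, the basement membrane laminin that hemidesmosomes bind. Its partner chain Lamb3 had a log2 fold change of 0.47 (limma adjusted p 0.985), and the integrin subunits that form its receptor did not pass, with Itgb4 at 0.74 (adjusted p 0.985) and Itga6 at -0.26 (adjusted p 0.985). Of the 30 integrin and adhesion genes tested, 6 had separated groups with higher and 8 with lower values in the positive cells and none passed; the ends of that range were L1cam at 0.89 (adjusted p 0.826) and Itgb6 at 0.87 (adjusted p 0.985), and Ceacam1 at -1.02 (adjusted p 0.985) and Itgb2 at -0.53 (adjusted p 0.985). The epithelial transcription factor Grhl2 was at 0.07 (adjusted p 0.993) and Elf3 at 0.48 (adjusted p 0.985). The oxidative enzymes Moxd1, at 1.12 (limma adjusted p 0.152), and Nox4, at 1.35 (adjusted p 0.278), had separated groups without passing under the main settings. Moxd1 passed with arrays centred on their median (limma adjusted p 0.0389). These genes were picked from the table after their values were seen.

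Of 47 epithelial genes tested, 5 were called higher in CD44v8-10-positive cells, and the list passed camera with its preset correlation but not with an estimated one (adjusted p = 0.557) or fry (0.263). Dilution of the negative samples by cells lacking epithelial transcripts could lower these genes, but it would lower all by a like factor. The log2 fold changes had a standard deviation of 0.891 over the 47 genes, against at most 0.315 in the other splits of the arrays. The called genes carry much of this: over the 42 not called it was 0.434, against at most 0.314. The spread therefore does not decide, since the called genes were picked in the real split. Krt8 and Krt18 had upper 95% bounds of 0.34 and 0.37, below the lower bound of 0.95 for Epcam, the called gene with the smallest difference. This argues against dilution as the whole cause for the called genes, with 2 limits. Krt8 and Krt18 were chosen after their values were seen, and Epcam was called in this same split, so its bound may be too high. A part of dilution in the differences stays open. Brightness of negative replicate 2 was argued against as well, since 8 of the 9 called genes passed without that array. Of the 3 ways to split the 4 arrays, 1, the real one, gave as many as 9 genes and the highest other gave 0, which is too few splits for a share under 0.05; a difference in state between the cells divided by CD44v8-10 stays open and was not tested.

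Postn was 7.03-fold higher in the positive cells, and fibroblasts in those samples are a possible explanation. The 5 fibroblast markers tested did not rise with it: the highest upper 95% bound of their log2 fold changes was 1.22, below the lower bound of 2.26 for Postn. Each compared with itself between groups, the 13 markers on the array differed by -0.94 to 0.49 (Fbln1 by 0.08, and by -0.43 with its tested probe set), among them the abundant fibroblast collagens Col1a1 (mean signals 5.85 in positive and 9.57 in negative cells), Col1a2 (45.2 and 43.4) and Col3a1 (11.1 and 10.9). These values argue against fibroblasts as the whole cause, by a rule revised after the values were seen, although 0 of the 5 tested markers were brighter than the median tested gene and 7 of the 13 had both group means below the filter level. Expression of Postn by the carcinoma cells themselves stays open and was not tested.

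Interferon genes passed camera when the arrays were split by replicate number (adjusted p 7.06e-09). Of 33 members, 26 were higher in replicate 1 than in replicate 2 of the positive cells, 29 in the negative cells and 24 in both, with median log2 differences of 0.26 and 0.43. Brightness of the arrays stays open: the smaller median was 0.261 with the same sign in both groups, and while the trimmed means (237 and 220, 196 and 345) order the replicates oppositely in the groups, the deposited medians (33.3 and 39.2, 28.6 and 52.3) make replicate 1 the dimmer array in both. A culture or processing day shared by arrays of the same number may be the source: their differences correlated by 0.116 over all genes, but the labels give no day, so this cannot be told apart from chance in 2 pairs, and no biological explanation was tested. Split by replicate number, the arrays gave 0 genes past the threshold by limma, 924 at an unadjusted p under 0.05, more than the 532 of the real split, and 8 lists past camera, including, with lower values in replicate 1, the epithelial (0.0371) and desmosome (0.0184) lists.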
